A study of Mus musculus with 2 samples.

How the data were processed

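The series holds 2 libraries from lung adenocarcinoma of C57BL/6 mice, 1 of the CD45-negative and 1 of the CD45-positive cells parted by magnetic beads. Per the series design text, 6000 cells were loaded per channel of a droplet 3' platform, libraries were read at 98 base pairs, and reads were demultiplexed, aligned to the mm10 transcriptome and collapsed by UMI with Cell Ranger 1.1.0. The submitters' processing notes name Cell Ranger and mm10. The deposited cell labels carry the name LucOS, which the sources do not explain. The number of mice, a description of the tumour model and its stage, and how the cell classes were made are not given in the sources used here. The authors deposited raw counts, unnormalized UMI per gene and cell, for both libraries in 1 table, and a table of cells with the library, a class, the total of UMI counts and the number of genes with a UMI. Both sums were checked and matched the deposited counts in all 15389 cells. No value was other than a whole number, and each gene in the table had a UMI in at least 3 cells. The genes of the T cell receptor chains (Trac, Trbc1, Trbc2, Trdc) are not in the table.

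The libraries were the groups: 3957 cells with 40873786 UMI in the CD45-negative and 11432 cells with 47477407 UMI in the CD45-positive library. The least deep cells had 4646 and 2204 UMI. The CD45-positive library thus holds more cells than were loaded per channel, and whether channels were merged is not given in the sources used here. With 1 library per group no p-value or standard error of a difference between the groups was made, and cells were not used as replicates. Intervals and percentiles describe the counts of these libraries. Levels were CPM of summed UMI with exact Poisson intervals, shares had exact Clopper-Pearson intervals, and ratios had exact conditional-binomial intervals, all at 95% and for counting error only. Ratios pooled over AT2 sub-clusters were Mantel-Haenszel rate ratios, with 95% intervals from resampled Poisson counts. A group with 0 UMI was set to 3 counts for a bound. Shares of cells with a UMI were also computed after thinning to 1000 UMI per cell, which dropped 0 cells. All deposited cells were kept and no doublets were removed. Scrublet, run in each library through scanpy, called 1 and 0 cells, so it gave no usable calls.

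The 7 deposited classes were used as given. Immune cells were clustered with scanpy 1.11.5 and igraph 0.11.9 (Leiden, resolution 1.0, 2000 variable genes, 30 components, 15 neighbours), and their T cells were clustered again in the same way. The AT2 and Endothelial classes were sub-clustered at resolution 0.5. Clusters were named from 33 marker lists, and 10 further lists (136 of 140 genes in the table) were left out of the clustering so that their genes could be compared. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene positions came from the mouse annotation of GRCm38.

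The marker and gene lists, comparisons, most alternatives and rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest ratios among genes with at least 500 UMI between the libraries, or at least 20 UMI between T cell groups, with Ptprc, Epcam, Il33 and Il1rl1 always. For Il33 and Il1rl1 it took the 5 classes with the highest CPM, the background class and Treg-like cells, and for lists by class up to 4 genes per list with at least 50 UMI and the IL-33 axis. A ratio of 2 counted as higher or lower. List medians were placed among 10000 random lists of equal size and like expression. Classes had at least 20 cells. The names of clusters, the score limits that picked T cells and the comparator of Treg-like cells, and the exclusion of sub-clusters led by NK and B cell markers (70 and 64 cells) from the T cell total were set after the data were seen. The comparator planned as other CD4 T cells turned out mixed and is named so. The sub-clusters of the AT2 and Endothelial classes were added after the data were seen as well.

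The computation was tested on simulated data. Between the libraries, simulated 2-fold and 4-fold changes were estimated at 2.00 and 4.02 (medians), intervals held the true value for 97% and 90% of them and for 95.2% of unchanged genes, and 0% of unchanged genes passed 2-fold. For the T cell comparison the estimates were 1.93 and 4.13, intervals held the true value for 96%, 95% and 96.2%, and 3.91% of unchanged genes passed 2-fold. Of unchanged lists, 3.5% and 2.5% lay outside the central 95% of random lists. The simulated counts were Poisson draws for each group, with no spread between cells or libraries. The test thus checks the computation, and coverage and the share of unchanged genes past 2-fold may be worse in the real counts. Alternatives covered the mean of per-cell levels, a filter on UMI and mitochondrial share, thinning, resolutions 0.5 and 2.0, Treg by a Foxp3 UMI, subtraction of background, removal of cells with high doublet scores or of mixed sub-clusters, other comparators, and leaving out the cell with the most UMI of each gene.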

Results

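Lung adenocarcinomas of C57BL/6 mice were dissected and dissociated, and the cells were parted with magnetic beads against CD45, the surface phosphatase carried by nearly all leukocytes. Each fraction was deposited as 1 droplet library of 3' transcript ends. The deposited table held 15389 cells. The CD45-negative library had 3957 cells and 40873786 UMI (unique molecular identifiers, counted transcripts), with a median of 7710 UMI per cell. The CD45-positive library had 11432 cells and 47477407 UMI, with a median of 3376 UMI per cell. That is more cells than the 6000 loaded per channel, and whether channels were merged is not given in the sources used here. There was 1 library per fraction and no replicate, so differences between the fractions could not be tested against variation between samples. All intervals below are 95% intervals, and like the floors for counts of 0 they cover counting error only. The series title names IL-33 signalling and the diversity of regulatory T cells in tumour development. The questions followed here are which cells of the tumour-bearing lung held the transcript of IL-33, which held that of its receptor ST2 (Il1rl1), and how cells resembling regulatory T cells (Treg) differed from other T cells.

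The CD45-negative library was made up mainly of alveolar and vascular cells. By the authors' annotation, 42.4% (40.8 to 43.9%) of its cells were alveolar type 2 (AT2) cells, the surfactant-producing epithelium, and 31.6% (30.1 to 33.0%) were endothelial. The class deposited as Fibroblast took 9.0% (8.12 to 9.93%) and alveolar type 1 (AT1) cells 7.20% (6.42 to 8.05%). None of the 7 deposited classes was named for tumour cells, so tumour cells within the AT2, AT1 or other classes were not told apart. Immune cells were 108 of 3957, or 2.73% (2.24 to 3.29%). The CD45-positive library held 65.1% (64.2 to 65.9%) immune cells, 19% (18.3 to 19.7%) endothelial cells and 11.6% (11.0 to 12.2%) AT2 cells, so that 34.9% (34.1 to 35.8%) of its barcodes carried a non-immune annotation. The magnetic sort sets these shares. Leukocyte transcripts were present in the non-immune classes of this library: Ptprc, which encodes CD45, had a UMI in 31.9% (29.9 to 33.9%) of its endothelial barcodes, against 1.12% (0.614 to 1.87%) of those in the CD45-negative library. The median depths were 3591 and 6808 UMI, and after thinning to 1000 UMI per cell the shares were 10.3% and 0.320%. Of the endothelial barcodes in the CD45-positive library, 1245 (57.3%) lay in sub-clusters led by leukocyte genes.

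The class deposited as Fibroblast carried the transcripts of mesothelium, the lining of the pleura. In the CD45-negative library its level of Msln was 3633 CPM (summed UMI per 1000000; 3570 to 3698), that of Upk3b 2189.7 CPM (2140.4 to 2239.8) and that of the mesothelial factor Wt1 194 CPM (180 to 209). The collagen-binding proteoglycan gene Dcn was high as well (3808 CPM, 3743 to 3874), but Pdgfra, a receptor of lung fibroblasts, had 2 UMI in 356 cells (0.584 CPM, 0.0707 to 2.11). When all cells were clustered together, 521 of the 527 cells of this class (98.9%, 98 to 99.6%) fell in the cluster led by mesothelial markers. Pdgfra (258 CPM, 229 to 290) and Inmt (2162 CPM, 2077 to 2249) marked a sub-cluster of the class deposited as Endothelial, with 120 cells in this library, which also held Pecam1, an endothelial adhesion molecule, at 751 CPM (701 to 804). The class is therefore called the Fibroblast class (mesothelial-like) below. This comparison of markers was chosen after the data were seen.

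**Figure D1:**
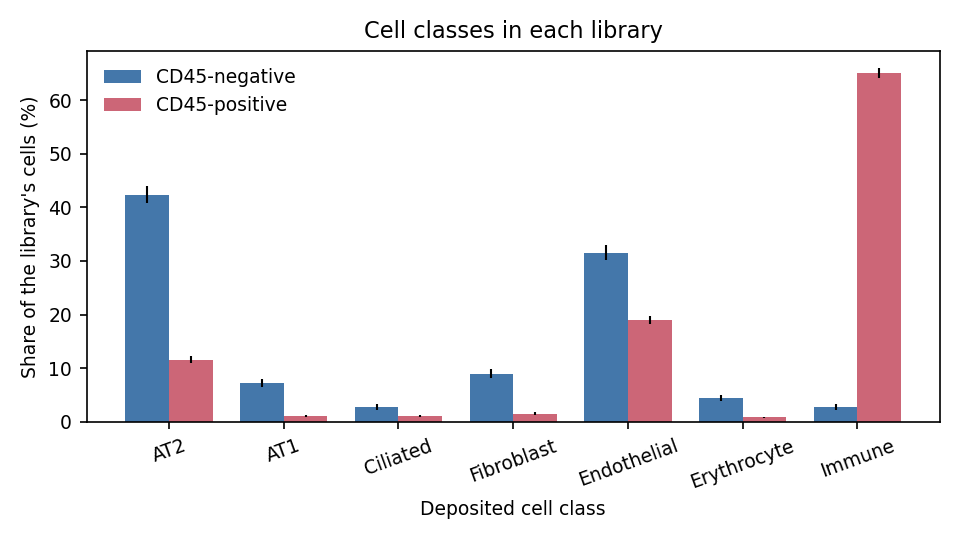
Share of each library's cells (percent, vertical axis) in each of the authors' classes (horizontal axis), blue for the CD45-negative and red for the CD45-positive library, with exact 95% binomial intervals as black lines. Immune cells make up 2.73% of the first and 65.1% of the second, while AT2 cells fall from 42.4% to 11.6%.

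Within the immune class of the CD45-positive library (7438 cells), clustering separated macrophages, lymphocytes, neutrophils and dendritic cells. Alveolar macrophage-like cells (the resident phagocytes of the airspace) were 13.8% (13 to 14.6%), B cell-like 12.7% (11.9 to 13.4%), plasma cell-like 12% (11.2 to 12.7%), neutrophil-like 7.73% (7.13 to 8.36%) and C1q macrophage-like 7.54% (6.95 to 8.17%). Mature dendritic cell-like cells were 0.955% (0.746 to 1.20%) and NK cell-like cells 0.941% (0.734 to 1.19%). Clusters that met no marker rule or mixed markers of several classes stayed unnamed and held 15% of the immune class. T cells, leaving out sub-clusters led by NK or B cell markers, numbered 1854. Of these, 11.6% (10.2 to 13.1%, 215 cells) fell in a Treg-like sub-cluster led by Tnfrsf4, Ikzf2, Foxp3 and Ctla4, among others. Foxp3, the lineage factor of Treg, had a UMI in 28.4% (22.5 to 34.9%) of them and in 4.14% (2.96 to 5.62%) of B cell-like cells, which should lack it, at median depths of 3098 and 2964.5 UMI. Thinned to 1000 UMI per cell, the shares were 9.77% and 0.849%. With coarser clustering the Treg-like cells merged with other T cells to 27.9% of them, and with Treg defined as T cells with a Foxp3 UMI their share was 6.90%. Only 61 of the 128 T cells with a Foxp3 UMI lay in the Treg-like sub-cluster. In the CD45-negative library, 52 of the 108 immune cells were alveolar macrophage-like and 22 plasma cell-like.

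Lymphocyte transcripts were higher in the CD45-positive library, and erythroid, mesothelial and epithelial transcripts were higher in the CD45-negative library. Ptprc stood at 207 CPM in the CD45-positive and 6.09 CPM in the CD45-negative library, a ratio of 33.9 (29.9 to 38.6). Epcam, an epithelial adhesion molecule, was 2.72-fold higher (2.61 to 2.83) in the CD45-negative library, and Il33 was 5.09-fold higher (4.72 to 5.49), at 90.8 against 17.8 CPM. All 7 measured leukocyte markers and all 6 T cell markers were at least 2-fold higher in the CD45-positive library, with median log2 ratios of CD45-negative over CD45-positive of -5.08 and -7.50. All 10 AT2 markers and all 6 mesothelial markers were at least 2-fold higher in the CD45-negative library, with medians of 1.71 and 2.44. All 5 erythroid markers were higher there as well, with the highest median of all lists (2.51), and so were all 7 epithelial markers (median 1.95). Of 9 fibroblast markers 7 were higher there (median 1.69), and of 10 endothelial markers 3 (median 0.96).

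The 12 highest ratios among 9960 genes with at least 500 UMI belonged to Gkn2 (10.6, 8.94 to 12.6), Ly6g6c (8.57), R3hdml (8.45), Scgb3a1 (8.34), Has1 (8.14), Gpc3 (8.12), Gm9780 (7.79), Phgr1 (7.29), Msln (7.24), Pkhd1l1 (6.94), Upk3b (6.90) and Pamr1 (6.84). Scgb3a1 encodes a secretoglobin of the airways, and Msln and Upk3b are mesothelial genes. The 12 lowest were led by genes with no UMI in the CD45-negative library. Against its floor of 3 counts, the chemokine genes Xcl1 and Ccl1 were at least 1288-fold and at least 1227-fold higher in the CD45-positive library, Tnfsf8 at least 589-fold, the enkephalin precursor Penk at least 396-fold, the checkpoint receptor Pdcd1 at least 363-fold and Izumo1r at least 349-fold. Sh2d2a was higher by a ratio of 531, the cytokine Il17a by 389, the T cell receptor subunits Cd3e, Cd3g and Cd3d by 369, 342 and 298, and the chemokine receptor Cxcr6 by 317. Altogether 1437 genes were at least 2-fold higher in the CD45-negative and 820 in the CD45-positive library. These sizes describe the 2 libraries and have no replicate check.

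Among the 10 gene lists kept out of the clustering, the tumour-progression list leaned to the CD45-negative library, with 10 of 15 members at least 2-fold higher there and a median log2 ratio of 1.61, above all 10000 random lists (percentile 100) matched on size and expression. The T cell lists leaned the other way. The sort by CD45 parts leukocytes from other cells, and the random lists were not matched on cell type. A list's direction and percentile can therefore follow from the cell types that express its genes. All 10 cytotoxic genes (median -6.62), 19 of 28 Treg effector genes (median -3.33) and 7 of 10 naive T cell genes (median -3.09) were at least 2-fold higher in the CD45-positive library, as were 13 of 23 chemokines (median -1.76) and 7 of 11 checkpoint ligands (median -1.57). The IL-33 axis list went both ways, with 2 members higher in each library and 8 between (median -0.15, percentile 4.23). Besides Il33, Areg was higher in the CD45-negative library (ratio 3.33, 3.22 to 3.44). Il1rl1 was 14.6-fold (9.08 to 24.9) and Il13 at least 17.5-fold higher in the CD45-positive library. The ratios of CD45-negative over CD45-positive were 1.27 for Map3k7, 1.01 for Myd88, 0.985 for Sigirr, 0.965 for Irak1, 0.845 for Il4, 0.695 for Traf6, 0.614 for Irak4 and 0.505 for Il1rap. Epithelial alarmins and cytokines had 5 higher in the CD45-negative and 4 in the CD45-positive library (median -0.24, percentile 1.25). MHC class II (median -0.43, percentile 1.84) and dissociation stress genes (median -0.06, percentile 14.9) had 1 member each past 2-fold, both higher in the CD45-positive library.

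Il33 transcripts were concentrated in AT2 cells and in the Fibroblast class (mesothelial-like). The AT2 class may include tumour cells, which had no class of their own. Il33 (ENSMUSG00000024810, a protein-coding gene on chromosome 19 from 29925114 to 29960718, plus strand, GRCm38) encodes an alarmin cytokine held in the nucleus of barrier cells. In the CD45-negative library its level was 161 CPM (148 to 175; 553 UMI) in the 356 cells of the Fibroblast class and 145 CPM (140 to 151; 2699 UMI) in 1677 AT2 cells. These levels were close, with a ratio of 1.11 (1.01 to 1.22), and the mean of per-cell levels put AT2 cells first. With finer clustering of all cells the highest level was 352 CPM, in 268 cells of an AT2 cluster led by Lyz1 and Scd1. AT1 cells followed with 57.8 CPM (51.6 to 64.6), ciliated cells with 23.0 CPM (15.7 to 32.5) and endothelial cells with 10.1 CPM (8.25 to 12.3). Too few B or T cells were present to give a background, so the immune class of 108 cells served, at 9.72 CPM (4.66 to 17.9). The endothelial level was close to background, and so was that of its Pdgfra and Inmt sub-cluster (12.5 CPM, 6.81 to 20.9). A sub-cluster of 87 endothelial cells led by Cytl1, Slc6a2 and Vwf, the last encoding von Willebrand factor, reached 36.7 CPM (23.8 to 54.2). The Fibroblast class and AT2 cells together supplied 87.6% (86.5 to 88.7%) of the library's 3711 Il33 UMI.

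An Il33 UMI was found in 62.1% (56.8 to 67.1%) of the Fibroblast class, 47.4% (45 to 49.8%) of AT2 cells and 9.26% (4.53 to 16.4%) of the background class, at median depths of 8025.5, 8143 and 7834.5 UMI. Thinned to 1000 UMI per cell, the shares were 15.2%, 11.7% and 0.926%. In the CD45-positive library the order by CPM was the same for the leading classes: the Fibroblast class 96.4 CPM (77.4 to 119), AT2 cells 84.0 CPM (77.5 to 90.8) and AT1 cells 25.1 CPM (17.4 to 35.0). The ratio of the Fibroblast class over AT2 cells was 1.15 (0.908 to 1.43), an interval that included equality. An unnamed immune cluster led by haemoglobin and surfactant transcripts came next at 10.0 CPM (5.6 to 16.5), then an unnamed cluster of 28 cells with 1 Il33 UMI (6.62 CPM). B cell-like cells, the background there, had 2.19 CPM (0.880 to 4.51), and Treg-like cells had 2 UMI, or 2.79 CPM (0.338 to 10.1). Of the AT2 barcodes in this library, 50.4% lay in a sub-cluster led by leukocyte genes and a further sub-cluster was led by endothelial genes, so AT2 values were compared between the libraries by sub-cluster. In the AT2 sub-cluster led by Lyz1 and Cbr2, Il33 stood at 400 CPM (372 to 429) in the CD45-negative and 288 CPM (228 to 360) in the CD45-positive library.

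**Figure D2:**
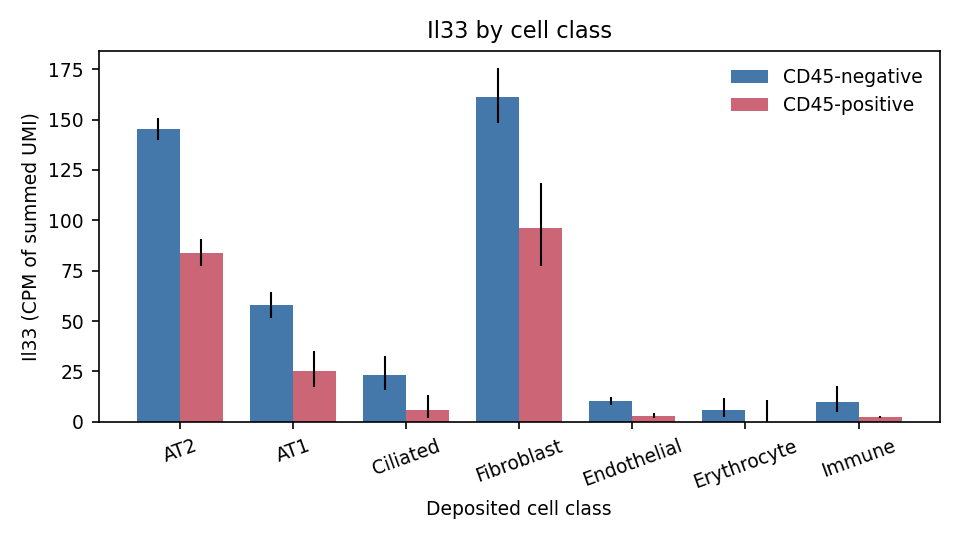
Il33 level (CPM of summed UMI, vertical axis) by the authors' class (horizontal axis) in the CD45-negative (blue) and CD45-positive (red) library, with exact 95% Poisson intervals. The Fibroblast class (mesothelial-like) reaches 161 and 96.4 CPM and AT2 cells 145 and 84.0 CPM, while immune cells stay at 9.72 and 2.43 CPM.

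Among the classes formed, the level of Il1rl1 was highest in Treg-like cells, though most Il1rl1 UMI lay in other classes. No class was named for innate lymphoid cells (ILC2) or for mast cells and basophils, which had marker lists, so their levels were not measured. Il1rl1 (ENSMUSG00000026069, a protein-coding gene on chromosome 1 from 40429570 to 40465415, plus strand, GRCm38) encodes ST2, the chain of the receptor that binds IL-33. In the CD45-positive library its level was 68.3 CPM (50.6 to 90.3) in the 215 Treg-like cells. They held 49 of the library's 305 Il1rl1 UMI, of which 250 (82.0%, 77.2 to 86.1%) lay in the immune class. Cycling T-like cells followed with 21.9 CPM (13.9 to 32.8) and neutrophil-like cells with 15.9 CPM (10.6 to 23.0). An unnamed cluster led by mitochondrial transcripts had 13.8 CPM (6.89 to 24.7), and an unnamed T sub-cluster with B cell markers had 12.5 CPM (2.58 to 36.5). AT2 cells, the background class fixed in advance, had 2.15 CPM (1.23 to 3.49), and B cell-like cells had 8.75 CPM (5.82 to 12.6). The level in Treg-like cells was 3.12-fold (1.87 to 5.37) that of cycling T-like cells and 7.81-fold (4.81 to 12.9) that of B cell-like cells. Against plasma cell-like cells it was 13.8-fold (8.07 to 24.6). Against a T sub-cluster named for Cd8b1 and Ly6c2 it was 70.6-fold (12.1 to 2844). The B cell-like level thus does not stand for all lymphocytes.

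An Il1rl1 UMI was found in 17.2% (12.4 to 22.9%) of Treg-like cells, 2.44% (1.55 to 3.64%) of B cell-like cells and 1.13% (0.635 to 1.86%) of AT2 cells, at median depths of 3098, 2964.5 and 4239 UMI. Thinned to 1000 UMI per cell, the shares were 8.37%, 0.849% and 0.453%. With coarser clustering, where 498 T cells formed the Treg-like group, the level was 32.1 CPM. The CD45-negative library held 18 Il1rl1 UMI in all. The Fibroblast class (mesothelial-like) had 13 of them (3.79 CPM, 2.02 to 6.49), AT1 cells 4 and endothelial cells 1. AT2 cells there had 0 UMI (floor of 3 counts, 0.162 CPM).

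**Figure D3:**
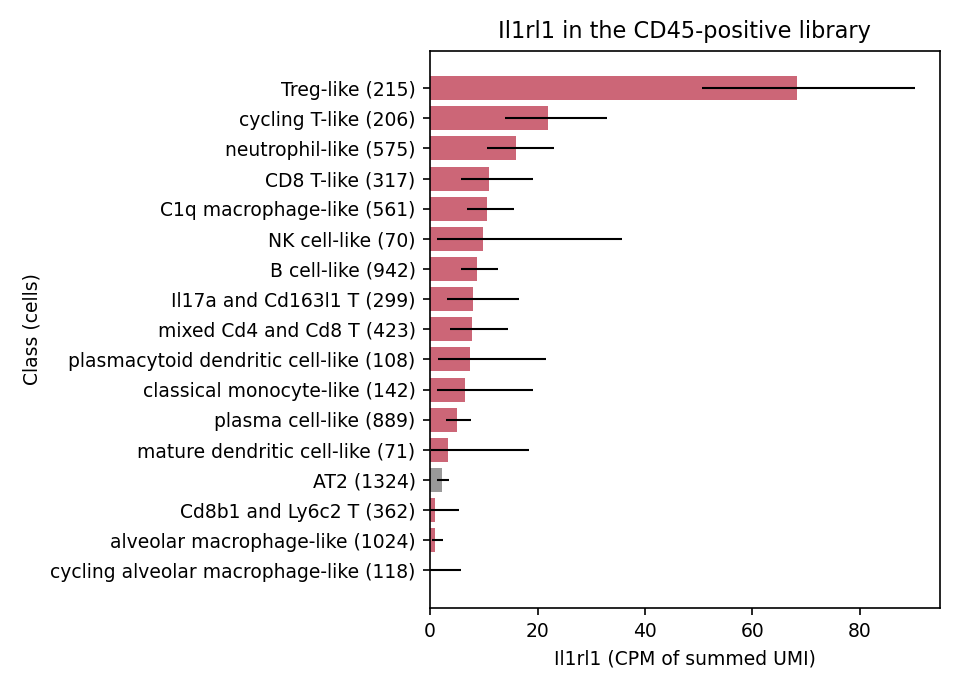
Il1rl1 level (CPM of summed UMI, horizontal axis) in the named immune classes of the CD45-positive library (vertical axis, with the number of cells of each), red for immune classes and grey for AT2 cells as the background, with exact 95% Poisson intervals as black lines. Treg-like cells stand at 68.3 CPM, above cycling T-like cells at 21.9 CPM and AT2 cells at 2.15 CPM.

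Treg-like cells carried more transcripts of Treg effector genes than the other T cells they were compared with. The comparison took 89 genes that had no part in the clustering, of which 24 were at least 2-fold higher in the 215 Treg-like cells and 5 at least 2-fold higher in the comparator of 423 cells. Of 26 measured Treg effector genes, 17 were at least 2-fold higher in Treg-like cells and none at least 2-fold lower. The median log2 ratio was 1.34, above all random lists (percentile 100). Treg-like cells were picked by their Treg markers, and genes that vary with these markers can be high even when left out of the clustering. The random lists were not matched on cell type or state. Here and for the lists below, a percentile can therefore follow from how the cells were picked. Tnfrsf9, a costimulatory receptor, was 16.1-fold higher (10.3 to 26.2), the IL-35 subunit gene Ebi3 10.1-fold (2.91 to 53.6), the anti-inflammatory cytokine gene Il10 9.59-fold (3.64 to 31.9) and Il1rl1 8.70-fold (4.36 to 19.3). The epidermal growth factor receptor ligand gene Areg was 8.27-fold higher (5.62 to 12.5) and the lectin receptor gene Klrg1 7.66-fold (4.40 to 14.1). The remaining genes among the 12 highest ratios were Tff1 (14.3), Havcr2 (5.13), Lrrc32 (4.0), Lag3 (2.93), Tnfrsf1b (2.92) and Cxcl10 (2.91). Lag3 was higher in CD8 T-like cells of this library, outside the comparator, than in Treg-like cells (596 against 131 CPM). So was Pdcd1 (307 against 120 CPM), another of the 17 genes. Havcr2 (48.5 against 36.3 CPM) and Tff1 (340 against 326 CPM) were closer. Treg-like cells were the top class of Tnfrsf9 (278 CPM, against 173 CPM in CD8 T-like cells), Il1rl1, Il10, Klrg1 and Tnfrsf1b. For Il10 (1.42-fold the next class, 0.495 to 5.59) and Tnfrsf1b (1.15-fold, 0.886 to 1.48) the intervals included equality. Ebi3 was higher in mature dendritic cell-like cells (49.7 against 23.7 CPM) and Lrrc32 in endothelial cells (53.4 against 25.1 CPM).

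Naive and cytotoxic T cell genes leaned to the comparator. None of 10 naive genes and none of 10 cytotoxic genes were at least 2-fold higher in Treg-like cells, and 2 of each were at least 2-fold lower, with medians of -0.65 and -0.62 (percentile 0 for both). Dapl1 was lowest, with 1 UMI in Treg-like cells and 58 in the comparator (ratio 0.0306, 0.000762 to 0.178). The ratio was 0.303 (0.115 to 0.683) for Igfbp4, 0.406 (0.287 to 0.563) for the NK receptor gene Klrk1 and 0.434 (0.259 to 0.698) for the granzyme gene Gzmk. Klf2 (0.557), S1pr1 (0.558) and Tcf7 (0.574), genes of T cell recirculation and the naive state, and Ccl3 (0.566), Ccl4 (0.576), Cxcr3 (0.576) and Ccl5 (0.576) were less than 2-fold lower. For the inflammatory chemokine genes Ccl3 and Ccl4, 1 comparator cell held 39 of 113 and 82 of 293 UMI. Without the top cell of each group the ratio was 0.769 (0.492 to 1.18) for Ccl3, an interval that included equality, and 0.675 (0.515 to 0.877) for Ccl4. A Ccl3 UMI was found in 12.1% of Treg-like, 6.62% of comparator and 7.54% of B cell-like cells, and a Ccl4 UMI in 17.2%, 16.3% and 11.1%, at median depths of 3098, 2764 and 2964.5 UMI. Thinned to 1000 UMI per cell, the shares were 3.26%, 2.84% and 2.55% for Ccl3 and 8.37%, 6.62% and 3.61% for Ccl4. Traf6, a signalling adaptor, stood at 0.296, with an interval that included equality (0.0559 to 1.01).

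The other lists moved less. Of 7 chemokines, 2 were at least 2-fold higher in Treg-like cells while the median was -0.52 (percentile 0). Without the top cell of each gene 1 was higher and the median was -0.38 (percentile 0.135). The tumour-progression list had 1 of 6 members higher (median 0.61, percentile 99.8). The IL-33 axis had 2 of 8 higher and 1 lower (median 0.45, percentile 95.3), and its other tested members Map3k7, Irak1, Irak4, Sigirr and Myd88 had ratios of 1.78, 1.49, 1.25, 0.770 and 0.740. Too few UMI were present to compare Il4 (5 in Treg-like cells and 0 in the comparator), Il33 (2 and 4), Il1rap (2 and 5) and Il13 (1 and 2). Checkpoint ligands had 3 of 7 higher (median 0.04, percentile 30.7), epithelial alarmins 0 of 3 (median 0.30, percentile 69.2), MHC class II 0 of 7 (median 0.30, percentile 85.3) and dissociation stress genes 1 of 11 (median -0.00, percentile 13.3). Without top cells the medians were 0.06 (percentile 41.0) for checkpoint ligands and 0.05 (35.2) for epithelial alarmins. They were 0.27 (84.5) for MHC class II, 0.01 (23.4) for dissociation stress genes and 0.33 (88.85) for the IL-33 axis. AT2 cells of the same library held Areg at 254 CPM, above the 208 CPM of Treg-like cells, while the comparator had 25.1 CPM.

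Neither T cell group was purely CD4 by its UMI. Of the 423 comparator cells, 59 had UMI of Cd4 alone, 200 of Cd8a or Cd8b1 alone and 27 of both. Of the 215 Treg-like cells, 38 had UMI of Cd4 alone, 66 of Cd8a or Cd8b1 alone and 20 of both, and among 942 B cell-like cells, which should lack both, the numbers were 67, 207 and 17. The Il1rl1 level of the comparator (7.85 CPM, 3.76 to 14.4) was close to that of B cell-like cells. Against T cells with a Cd4 UMI and no Cd8 UMI, the Il1rl1 ratio was 11.2 and the median of the Treg effector list 1.04, over 24 genes. This group had 142 cells, and no interval was computed for its ratio. The 423 cells of the main comparator held 10 Il1rl1 UMI, so the ratio against the smaller group may rest on very few.

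**Figure D4:**
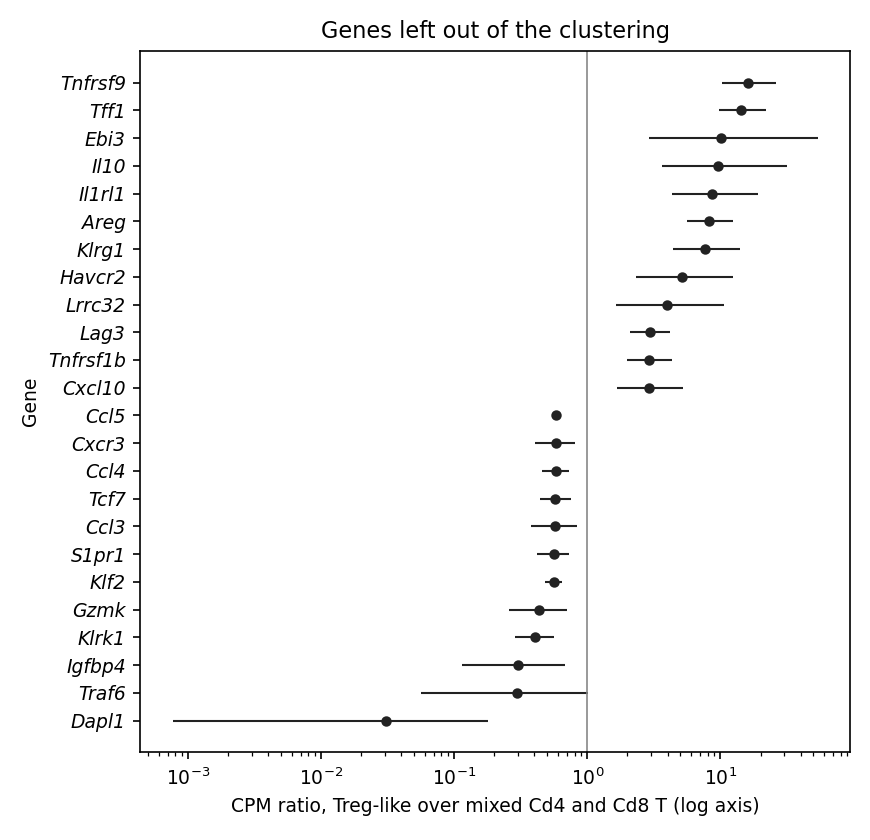
Ratio of CPM in Treg-like cells over the mixed Cd4 and Cd8 T comparator (horizontal log axis) for the genes with the 12 highest and 12 lowest ratios (vertical axis), as points with exact 95% conditional-binomial intervals and a grey line at a ratio of 1. Tnfrsf9 lies highest at 16.1, Il1rl1 at 8.70 and Dapl1 lowest at 0.0306.

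The lists differed in how many of their genes had a class well above the others. No class was named for tumour cells, so the values of the AT1 and AT2 classes may include them. In the CD45-negative library, 9 of 15 tumour-progression genes had a top class at least 2-fold above the next, among them Hmga2 in AT1 cells (27.2 CPM, 34.0-fold, 6.00 to 1351), Lcn2 in AT2 cells (2956 CPM, 11.2-fold), Gkn2 in AT2 cells (71.6 CPM, 10.4-fold) and the tight-junction gene Cldn4 in AT1 cells (658 CPM, 9.18-fold). Of 13 epithelial alarmins and cytokines 6 did so: Tgfb2 (353 CPM, 21.1-fold, 17.9 to 24.9) and the macrophage growth factor gene Csf1 (199.9 CPM, 7.25-fold) in the Fibroblast class (mesothelial-like), Tslp in AT1 cells (112 CPM, 8.55-fold) and Il1b in immune cells (159 CPM, 8.93-fold), with Il6 and Csf2 in ciliated and AT1 cells. Of 18 chemokines 14 did so, led by Ccl6 in immune cells (6306 CPM, 218-fold), Ccl9 in immune cells (33.1-fold), Ccl7 in the Fibroblast class (22.5-fold, 3.92 to 901, with 1 UMI in the next class) and Cxcl12 in endothelial cells (381 CPM, 9.51-fold). The counts were 2 of 9 for the IL-33 axis, 9 of 15 for Treg effector genes, 5 of 7 for naive T cell genes, 1 of 2 for cytotoxic genes, 2 of 6 for checkpoint ligands, 2 of 8 for MHC class II and 1 of 11 for dissociation stress genes. Within the IL-33 axis, Areg was highest in AT1 cells (1196 CPM, 3.95-fold, 3.81 to 4.09) and Sigirr in endothelial cells (43.1 CPM, 2.07-fold), while the top classes of Il1rap, Irak1, Myd88, Traf6, Map3k7 and Irak4 were less than 2-fold above the next.

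In the CD45-positive library, C1q macrophage-like cells were the top class of 7 of 8 MHC class II genes, with Cd74 at 25055 CPM (1.80-fold the next class), and none of the 8 genes passed 2-fold. Of 22 chemokines 10 did so, among them Ccl8 and Ccl12 in C1q macrophage-like cells (402 and 123 CPM, 7.79-fold and 6.30-fold) and Ccl1 in CD8 T-like cells (1804 CPM, 2.55-fold, 2.34 to 2.78). Mature dendritic cell-like cells were the top class of 4 of 10 checkpoint ligands, with Cd80 at 69.5 CPM (2.63-fold, 0.886 to 10.5) and Cd86 at 285 CPM (1.72-fold), and 1 of the 10 passed 2-fold. Treg-like cells were the top class of 9 of 27 Treg effector genes, of which 4 passed 2-fold in any class, with Klrg1 at 96.2 CPM (2.73-fold, 1.81 to 4.19). The IL-33 axis had 3 of 11 past 2-fold: Areg in AT1 cells (3.65-fold), Il1rl1 in Treg-like cells and Il13 in CD8 T-like cells (2.81-fold, 0.832 to 14.7). Its other members Irak1, Traf6, Myd88, Il1rap, Il33, Map3k7, Irak4 and Sigirr did not. The counts were 5 of 13 for tumour-progression genes, 3 of 12 for epithelial alarmins, 3 of 10 for naive T cell genes, 0 of 10 for cytotoxic genes and 0 of 11 for dissociation stress genes.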

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

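Both tests of the leukocyte transcripts and both tests of the lower Il33 level were chosen after the result was seen.

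Leukocyte transcripts appeared in barcodes that the authors placed in non-immune classes of the CD45-positive library, where no comparison looked for them. Ptprc stood at 111 CPM in its Endothelial class, 69.2 CPM in its AT2 class and 80.1 CPM in its Fibroblast class, against 2.03, 1.29 and 2.63 CPM in the CD45-negative library. Free RNA of 1 mixture in every droplet would give each barcode the same share of T cell transcripts among leukocyte marker UMI. Their variance was 7.19 times the binomial variance over 2600 barcodes (simulated range 0.944 to 1.05). The test takes all these UMI as foreign. Marker transcripts made by the cells themselves would widen the variance too, so it does not decide the question. A whole leukocyte added to a typical cell would raise the depth, but AT2 barcodes of the leukocyte-led sub-cluster had 0.699 times the median UMI of the others (3600 against 5151), and endothelial ones 0.908 times. Free RNA of 1 mixture, partial cells, aggregates of small cells and damaged cells may contribute. If channels were merged, so may free RNA that differed between them. These were not told apart, and no biological explanation was tested.

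The Il33 level of the AT2 class was 1.73-fold (1.59 to 1.89) higher in the CD45-negative than in the CD45-positive library. Without the sub-clusters of mixed barcodes the ratio was 1.60 (1.43 to 1.79), so their RNA was not the whole cause. Pooled over the same 5 unmixed sub-clusters as a Mantel-Haenszel rate ratio it was 1.37 (1.23 to 1.53). Different shares of the sub-clusters were thus not the whole cause either, though both steps lowered it. The surfactant gene Sftpb had a pooled ratio of 1.44 (1.42 to 1.45), while Sftpc had 0.974, Cxcl15 1.05 and Lyz2 1.06, so the remaining difference was not particular to Il33. A difference between the sorted fractions or their preparation may remain and cannot be separated with 1 library each.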

How the results depend on the processing

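The removal of mixed sub-clusters and of the highest 10% of doublet scores, the subtraction of the B cell-like level, leaving out the cell with the most UMI of each gene, and the comparators made of all other T cells or of T cells with a Cd4 UMI and no Cd8 UMI were chosen after the data were seen. None of the values counted here changed direction. Outside them, without top cells the dissociation stress median went from -0.00 to 0.01. Between Treg-like cells with and without an Il1rl1 UMI the ratio went from 1.38 to 0.655 for Prdm1, from 1.24 to 0.959 for Tnfrsf1b and from 1.06 to 0.965 for Itgae. All intervals of these ratios included equality. Of the alternatives fixed in advance 30 values stayed within the counting interval of the reported value and 13 left it, and of the added ones 15 and 4. Some values that stayed had no room to move. Thinning dropped 0 cells and so left the shares of cells as they were. Removing high doublet scores kept all 215 Treg-like cells, and removing mixed sub-clusters kept all 356 cells of the Fibroblast class. Thinning moved the Ptprc ratio to 29.8, the Il33 ratio to 6.09, the Il1rl1 level of Treg-like cells to 97.7 CPM and the Treg effector median to 1.08. Thinned values rest on fewer UMI, and the intervals do not cover their own counting error, which may contribute to these moves. The Il33 ratio was 6.42 with the mean of per-cell levels and 6.53 without mixed sub-clusters. The immune share of the CD45-positive library was 63.6% and 68.4% at resolutions 0.5 and 2.0, and 66.9% without high doublet scores. The highest Il33 level was 181 and 352 CPM at these resolutions, in clusters of 378 and 268 cells. At resolution 0.5 the Treg-like group of 498 cells had 32.1 CPM of Il1rl1 and took 27.9% of T cells, since it held other T cells too. By a Foxp3 UMI the Treg share was 6.90% and the effector median 1.005. That median was 1.06 against all other T cells and 1.04 against T cells with a Cd4 UMI and no Cd8 UMI. The main median (1.34) was over 26 genes with enough UMI, and these were over 20 (thinned), 23 (Foxp3 UMI), 27 (all other T cells) and 24 (Cd4 UMI), so the set of genes changed as well. The cause was not tested except at resolution 0.5. The Il1rl1 ratio stayed within its interval in all alternatives that gave one, between 6.86 and 16.8. That interval is wide (4.36 to 19.3). The highest value, at resolution 2.0, was against 228 comparator cells and had no interval of its own. Leaving out doublets called by Scrublet gave no value, since 1 and 0 cells were called, and resolution 0.5 gave no comparator and so no ratio or list median. Counting error is large for genes with few UMI, such as Il1rl1 in the CD45-negative library with 18.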

Other observations

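The prediction for the test of cells with an Il1rl1 UMI was written before its result was seen. The other values in this part were chosen after the data were seen.

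AT2 cells differed in Il33 between sub-clusters of the CD45-negative library. The sub-cluster led by Lyz1, Cbr2, Hc and Scd1 had 400 CPM (372 to 429) in 237 cells. The sub-cluster led by Ccl20 and Meg3 had 104 CPM (96.8 to 112) in 547 cells, cycling AT2 cells had 96.3 CPM (77.5 to 118), and the sub-cluster led by Gkn2, Cldn4 and Areg with AT1 markers had 93.3 CPM (84.3 to 103). The background of this library was 9.72 CPM.

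The class deposited as Endothelial held a sub-cluster of 413 cells with pericyte markers. In its 221 cells of the CD45-negative library, Pdgfrb stood at 235 CPM (213 to 258) and Pecam1 at 872 CPM. An unnamed immune cluster of 28 cells led by Pf4, Saa3 and Prg4 had the highest levels of Il6 (377 CPM, 11.1-fold the next class), Cxcl1 (450.2 CPM, 6.64-fold) and Ccl24 (271 CPM, 6.4-fold) in the CD45-positive library.

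Treg-like cells with an Il1rl1 UMI were richer in other effector genes than those without. The 37 cells with and 178 without had median depths of 3043 and 3099 UMI, and the median log2 ratio over 22 effector genes was 0.48, above all matched random lists (percentile 100), with 5 at least 2-fold higher and 2 lower. Il10 was 5.72-fold higher (2.49 to 13.2), Areg 4.83-fold (3.45 to 6.75) and the Treg marker Il2ra 2.78-fold (1.88 to 4.08), while Foxp3 (1.41, 0.787 to 2.39), Ctla4 (1.19) and Ikzf2 (0.951) were closer to equality. By share of cells the differences were smaller, with an Il10 UMI in 18.9% (7.96 to 35.2%) against 6.74% (3.53 to 11.5%) of cells and an Areg UMI in 54.1% (36.9 to 70.5%) against 26.4% (20.1 to 33.5%). Thinned to 1000 UMI per cell, the shares were 13.5% against 3.37% for Il10 and 35.1% against 11.2% for Areg. B cell-like cells, at a median of 2964.5 UMI, had an Il10 UMI in 1.49% (thinned 0.531%) and an Areg UMI in 4.03% (thinned 1.27%). Without the top cell of each group the ratios were 4.44 (1.63 to 11.8) for Il10 and 4.54 (3.15 to 6.53) for Areg, and the median over the effector genes was 0.33 (percentile 100), with 4 at least 2-fold higher and 1 lower. The percentiles restate this difference and do not say why it arose, and cells of other kinds within the Treg-like cluster were not told apart.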
